A study of Mus musculus with 6 samples.

How the data were processed

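The series measured poly(A) RNA in wild-type mouse embryonic fibroblasts (MEFs), primary cells grown out of mouse embryos. Cells labelled non-senescent were at passage 1 (P1) and cells labelled senescent were at passage 6 (P6), where a passage is a replating of the culture. At each passage 1 library came from vehicle-treated cells, 1 from cells given 20 µM α-amyrin and 1 from cells given 20 µM β-amyrin for 3 days, 6 libraries in all. The labels give no replicate of any of these 6 conditions.

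Per the labels' protocols, poly(A) RNA was purified from total RNA and made into libraries with a directional (strand-keeping) kit. Per the submitters' processing notes, the tools were FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9 and featureCounts 1.6.3 on the mouse build mm10; their settings, including whether counting used strand, are not given in the sources used here. The authors deposited whole-number read counts per gene for 55487 genes, not normalized, which were the input of every main test. The authors also deposited FPKM values (read values scaled for gene length and library size) for the same genes. The FPKM values were not a fixed multiple of the deposited counts within a gene; how they were computed is not given in the sources used here, and they entered only as alternatives.

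Total counts per library ran from 18798418 in P6 α-amyrin to 28752332 in P1 α-amyrin. Counts were scaled by TMM and written as CPM, counts scaled to a common library size. The 16962 genes that passed the filterByExpr function of edgeR, with passage as the group, were tested. With 1 library per condition, no difference between 2 single libraries has a replicate check. Nothing in the labels says that the libraries of a passage came from separate cultures or embryos, so the p-values of single genes measure only the spread among these libraries. Nor do the labels say that P6 came from the same MEF isolate as P1, so any difference between P6 and P1 could be one between isolates.

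The main test was the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest) in R 4.3.3. It fitted treatment and passage as additive terms to all 6 libraries and called genes at a Benjamini-Hochberg adjusted p below 0.05. This leaves 2 residual degrees of freedom, which come from the passage-by-treatment departures from additivity; a response that differs between passages therefore counts as error. The moderated fit added 4.83 prior degrees of freedom, and the common biological coefficient of variation was 7.72%. The terms reported were P6 against P1, each compound against vehicle, and α-amyrin minus β-amyrin. A passage-by-amyrin term was fitted with the α- and β-amyrin libraries of a passage taken as 2 samples of 1 amyrin group. Errors of log2 fold changes are standard errors derived from the test statistic, and intervals are 95% intervals from the same fit.

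Pairs of single libraries were described without a p-value, by the log2 ratio of CPM with a prior count of 2. A gene counted as changed by size when the ratio was at least 2-fold and CPM was at least 5 in at least 1 library of the pair. In total 34 gene lists were fixed, and 32 had enough tested members. They were tested with camera (limma 3.58.1) at the preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. At the preset correlation the p-value measures spread among genes. Estimated correlations in the additive fit were 0.81 for cholesterol synthesis, 0.87 for macrophage markers and 0.68 for interferon-stimulated genes. For such lists the preset correlation gives p-values that are too small. With an estimated correlation the test has only the 2 residual degrees of freedom, so calls can be lost whatever the correlation. Member counts are given over all genes tested and adjusted over the list alone. For single pairs, the median of a list was ranked among 10000 random lists of the same size matched on mean expression. Random lists were not matched on how far their genes change together, so the rank is no check on variation between cultures.

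Correlations of compound effects were computed across genes with CPM at least 5 in every library, for pairs of ratios that share no library and for pairs that share the vehicle library. The latter were set beside 50 simulations of libraries with no compound effect. The effect of each compound at P6 on passage-changed genes used passage changes measured in the libraries of the other compound, because a passage change from the vehicle libraries shares the P6 vehicle library with the compound ratio. These gene sets, too, held only genes with CPM at least 5 in every library.

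Genes were named by rule. For passage these were the 10 highest and 10 lowest log2 fold changes among called genes with mean CPM at least 5 and the same direction in every treatment, plus up to 3 members per list with the smallest adjusted p. For the compounds, called genes were named likewise, and where fewer than 5 passed in a direction, the 5 genes with the largest smaller ratio of both passages were named as chosen by size. A fixed set (Cdkn2a, Cdkn2b, Cdkn1a, Trp53, Lmnb1, Mki67, Il6, Cxcl1, Ccl2, Mmp3, Hmgcs1, Abca1, Hmox1, Nqo1 and Igf2) was examined in every comparison; other members of the set and of the lists are not reported here. Predicted genes and pseudogenes were counted but not named, except where the text says that a gene was chosen after its values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

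The test was tested on simulated counts drawn for the 16962 genes from the means and sizes of these libraries. For the passage term it recovered 62.7% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 11 unchanged genes called. For the α-amyrin term the shares were 53.7%, 85.1% and 97.0%, again with 11 unchanged genes called. The simulated spread was set by mean expression alone, with no departures from additivity. Such departures are the error of the real fit. The shares therefore do not tell how many real compound changes of these sizes the test would find. The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM at least 1 in at least 2 libraries, each library left out in turn, no treatment term, and both compounds as 1 amyrin group. Other prior counts, CPM minimums and passage thresholds were tried for the descriptions of single libraries. Leaving out genes at least 2-fold lower in the P1 β-amyrin than in the P1 α-amyrin library, and list tests of the passage-by-amyrin term, were added after the data were seen. Genes so left out also had CPM at least 5 in at least 1 of these 2 libraries.

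Genes with near-identical copies are uncertain where reads could be shared, as for ribosomal protein genes such as Rpl7a, which have many processed copies; how such reads were counted is not given in the sources used here. Overlapping and antisense genes are likewise uncertain, because the use of strand in counting is not stated.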

Results

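RNA was measured in 6 libraries of mouse embryonic fibroblasts (MEFs), which enter replicative senescence within a few passages in standard culture. P1 cells were labelled non-senescent and P6 cells senescent, and each passage had 1 vehicle, 1 α-amyrin and 1 β-amyrin library. α-Amyrin and β-amyrin are isomeric pentacyclic triterpene alcohols of plants. They have an ursane and an oleanane skeleton, which differ in the placement of a methyl group on ring E, and both were given at 20 µM for 3 days. Total counts were 26136738, 28752332 and 25077506 in the P1 vehicle, α-amyrin and β-amyrin libraries and 23826025, 18798418 and 25440191 in the P6 ones. Mitochondrial genes took 1.55% to 1.81% of counts. Passage separated the libraries on the first principal component, which held 83.1% of the variance. No condition had a replicate library.

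The first comparison asked how P6 cells differed from P1 cells. Genes of the cell cycle were lower and the senescence marker Cdkn2a was higher at P6. Cdkn2a, which encodes the p16 and p19 inhibitors of the cell cycle (ENSMUSG00000044303, mm10 chromosome 4, 89274471 to 89294653), rose by 2.68 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 9.71e-07), from 19.4, 17.2 and 17.4 CPM in the P1 vehicle, α-amyrin and β-amyrin libraries to 115, 116 and 115 CPM at P6. Cdkn2b, the neighbouring p15 inhibitor, rose by 0.52 ± 0.06. Cdkn1a, which encodes the p21 inhibitor, had a log2 change of 0.01 ± 0.04 (edgeR adjusted p = 0.92) at 524 to 572 CPM. Trp53, the p53 tumour suppressor, fell by 0.62 ± 0.04. Lmnb1, the nuclear lamina protein lamin B1 whose loss is a known marker of senescence, fell by 2.04 ± 0.06, and the proliferation marker Mki67 fell by 0.92 ± 0.06.

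**Figure D1:**
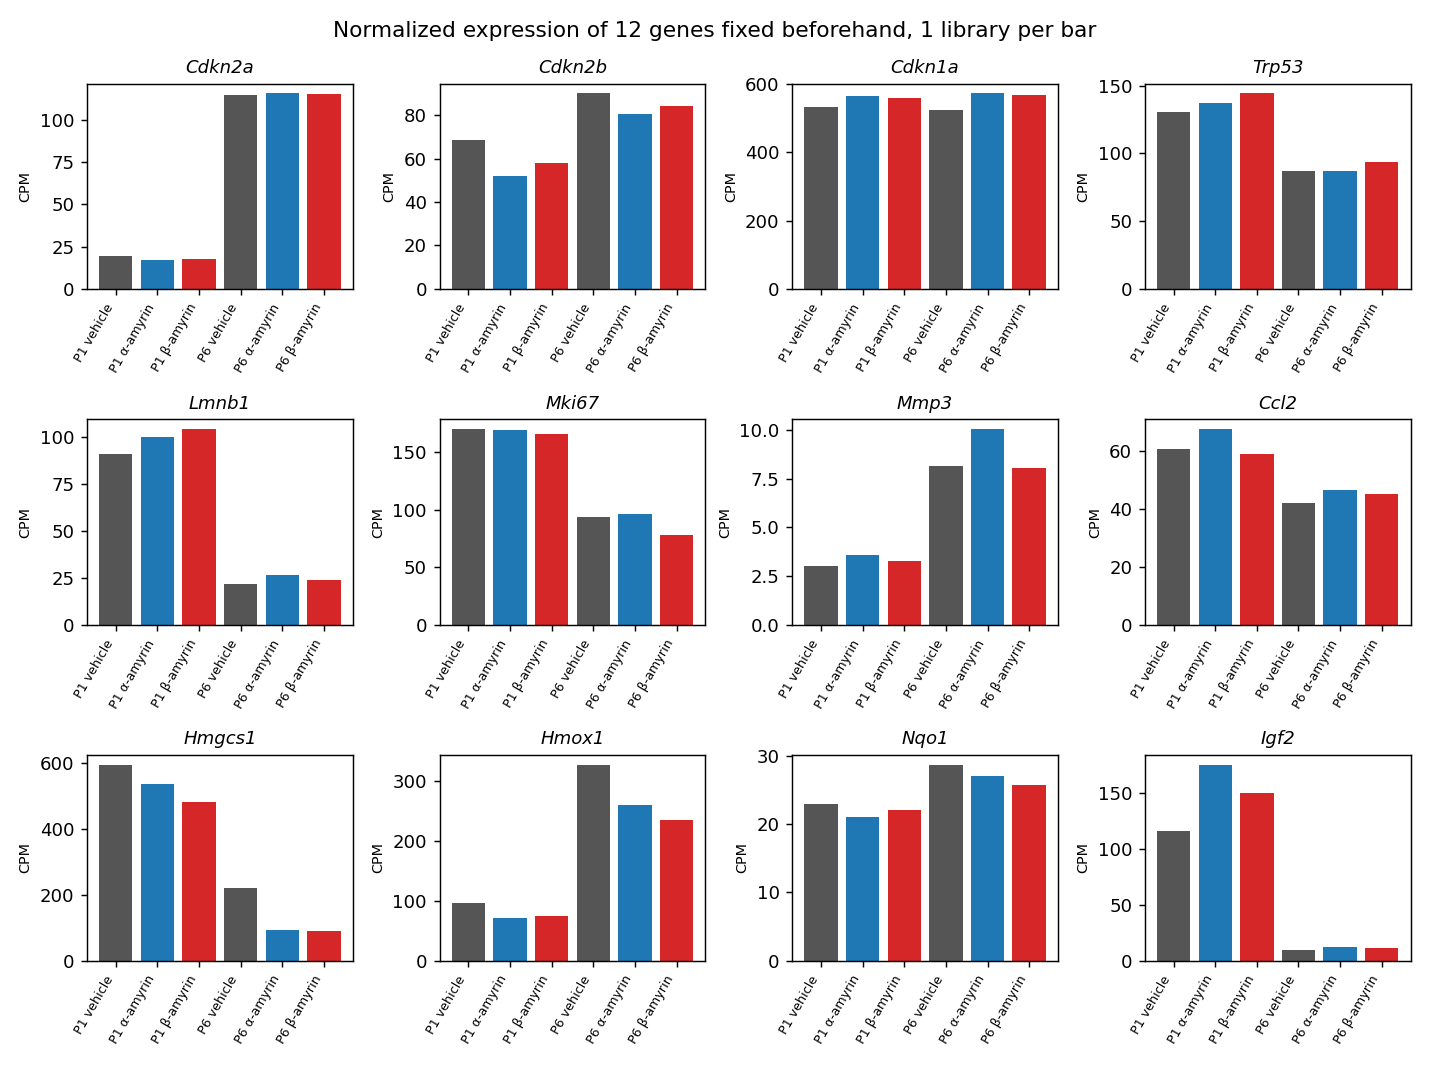
Each bar is the TMM-normalized expression of a gene in 1 library, in CPM on a linear axis from 0, for P1 and P6 cells given vehicle (grey), α-amyrin (blue) or β-amyrin (red). Cdkn2a lay at 17.2 to 19.4 CPM in the P1 libraries and at 115 to 116 CPM in the P6 libraries, while Hmgcs1 at P6 was 221 CPM with vehicle and 91.2 and 90.8 CPM with the compounds.

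Of 65 measured genes of G2/M and mitosis, 64 fell and 1 rose at P6, with a median log2 change of -1.22. Top2a, a topoisomerase of dividing cells, fell by 1.29 ± 0.05, the cyclin gene Ccnb1 fell by 1.52 ± 0.06 and Cdc20 fell by 1.46 ± 0.06. Of 57 genes of G1/S and DNA replication, 52 fell and 3 rose, with a median of -0.96. Rrm2 and Rrm1, the ribonucleotide reductase subunits, fell by 1.55 ± 0.05 and 1.43 ± 0.05. Adjusted over the list alone the counts were the same for both lists. By camera the adjusted p values with the preset correlation were 4.19e-23 for mitosis and 1.5e-14 for replication; with an estimated correlation the adjusted p values were 0.295 and 0.383. Among 42 p53 targets, 16 rose and 12 fell, and the list was not called (camera adjusted p = 0.50).

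Genes of cholesterol synthesis and of protein synthesis fell at P6. Of 27 genes for cholesterol synthesis enzymes and other SREBP2-regulated proteins, 26 fell and none rose, with a median of -1.80. Hmgcs1, the synthase that feeds the pathway, fell by 2.12 ± 0.20, and Dhcr7, the reductase of its last step, fell by 1.80 ± 0.11. The fall was smaller in the vehicle pair: the list median was -1.22 with vehicle, -2.10 with α-amyrin and -1.98 with β-amyrin, and the log2 ratio of Hmgcs1 was -1.43, -2.55 and -2.40. Abca1, a cholesterol exporter, rose by 2.40 ± 0.15. Of 56 ribosomal protein genes 55 fell, with a median of -0.48, and of 46 nuclear genes of oxidative phosphorylation 32 fell and none rose, with a median of -0.21; in the vehicle pair its median of -0.17 lay within the range of matched lists. Of 44 genes of the unfolded protein and integrated stress responses 28 fell and 7 rose. With the preset correlation the camera adjusted p values were 1.52e-10 for cholesterol synthesis, 2.61e-16 for ribosomal proteins, 2.94e-06 for oxidative phosphorylation and 0.000941 for the stress responses. With an estimated correlation the adjusted p values were 0.406, 0.339, 0.397 and 0.525.

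Lysosomal and antioxidant genes were higher at P6 in each treatment, and interferon-stimulated genes in the vehicle and β-amyrin pairs. Of 57 lysosome and autophagy genes 50 rose and 1 fell, with a median of 0.75; the lysosomal mannosidase gene Man2b1 rose by 2.04 ± 0.05 and the cathepsin gene Ctsf by 1.84 ± 0.06. Of 37 NRF2 targets 22 rose and 6 fell. Hmox1, the haem oxygenase of the oxidative stress response, rose by 1.76 ± 0.05, and Nqo1, an NRF2-regulated quinone reductase, rose by 0.30 ± 0.07. Of 53 interferon-stimulated genes 27 rose and 3 fell, among them the MHC class I genes H2-K1, which rose by 1.61 ± 0.07, and H2-D1, which rose by 2.44 ± 0.14. The interferon list had medians of 0.61 with vehicle and 0.78 with β-amyrin, and of 0.12 with α-amyrin, where 30 genes were higher and 23 lower and the median lay within the range of matched lists. The camera adjusted p values were 1.14e-13, 0.00232 and 0.00195; with an estimated correlation the adjusted p values were 0.397, 0.339 and 0.613. Macrophage markers rose in the same libraries, with a median of 4.12.

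Markers of macrophages, immune cells that embryo cultures can hold, were the list with the highest median change of the 32 tested at P6. All 19 measured markers rose, with a median log2 ratio of 3.67 in the vehicle pair, 3.58 with α-amyrin and 6.53 with β-amyrin. Lyz2, the macrophage lysozyme, went from 136, 85.6 and 17.6 CPM in the P1 vehicle, α-amyrin and β-amyrin libraries to 2704, 2630 and 2159 CPM at P6, a log2 change of 5.30 ± 0.49. Csf1r, the receptor for the macrophage growth factor CSF1, rose by 3.73 ± 0.22, and the complement gene C1qa by 4.73 ± 0.45. The 10 highest changes among called genes were Ms4a14, Lyz2, Ms4a7, Dennd1c, Il10ra, Csf2rb2, Cxcr4, C1qa, Pirb and Fcrls, at 4.71 to 5.39. By camera the adjusted p for the markers was 8.39e-08, and with an estimated correlation the adjusted p was 0.413.

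Markers of other lineages fell, although a change of isolate between passages would give such differences too. The 10 lowest changes were Gata4, Lrrn4, Gpm6a, Wt1, Upk3b, Podxl, Msln, Crb2, Myh6 and Bnc1, at -7.51 to -5.00. Msln, the mesothelial surface protein mesothelin, went from 30.6 to 37.0 CPM at P1 to 0.69 to 0.96 CPM at P6; Wt1 is a transcription factor of mesothelium and kidney, and Myh6 encodes a cardiac myosin. Among marker lists, 9 of 13 skeletal muscle genes fell and 1 rose, 12 of 14 cartilage and bone genes fell and 2 rose, 5 of 7 epithelial genes fell, 5 of 7 endothelial genes fell and 1 rose, and 8 of 14 neural and glial genes fell and 3 rose. Des, the muscle filament desmin, fell by 4.56 ± 0.08. Of 21 fibroblast markers 13 fell and 3 rose; Pdgfra, a growth factor receptor of fibroblasts, fell by 2.46 ± 0.08. Among 20 imprinted and fetal growth genes 17 fell and 1 rose, with Igf2, a fetal growth factor, lower by -3.74 ± 0.06 and the adjacent noncoding H19 lower by -3.19 ± 0.04. With the preset correlation the camera adjusted p values were 0.00236 for muscle, 0.00176 for cartilage and bone, 0.00373 for epithelial, 0.0198 for endothelial, 0.205 for neural, 0.00315 for fibroblast and 5.18e-07 for imprinted genes. With an estimated correlation the adjusted p values were 0.339, 0.383, 0.339, 0.406, 0.613, 0.339 and 0.339.

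Secreted factors of the senescence-associated secretory phenotype went both ways. Of 60 measured, 27 rose and 21 fell at P6 (29 and 22 adjusted over the list alone), and the list was not called (camera adjusted p = 0.30). Macrophage markers rose by a median of 4.12 in the same libraries. Among 45 of these factors with mean CPM at least 5, 23 were at or below 0 in the P1 α- over β-amyrin ratio. Those 23 had a P6 over P1 vehicle median of -0.04, and the factors above 0 had 0.42. Of the 45, 0 were both at least 2-fold lower in the P1 β- than the P1 α-amyrin library and at CPM at least 5 in either. Without that CPM minimum, 7 of the 60 factors were at least 2-fold lower in the P1 β-amyrin library and 2 at least 2-fold higher. Cxcl15, a chemokine, rose by 4.65 ± 0.15, and Mmp3, a matrix-degrading protease, rose by 1.41 ± 0.12. Ccl2, a chemokine that attracts monocytes, fell by 0.48 ± 0.06. Il6 was near 1 CPM in every library, with a log2 change of -0.06 ± 0.39, and Cxcl1 had a change of 0.75 ± 0.28 (edgeR adjusted p = 0.0552). Of 58 collagen and matrix genes 31 fell and 15 rose; Eln, which encodes elastin, fell by 2.96 ± 0.07. Of 36 contractile and TGF-beta-responsive genes 21 fell and 7 rose. The matrix median of -0.21 in the vehicle pair and the contractile median of -0.18 in the α-amyrin pair lay within the range of matched lists. The camera adjusted p values of the last 2 lists were 0.00613 and 0.00236, and with an estimated correlation the adjusted p values were 0.339 and 0.406.

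**Figure D2:**
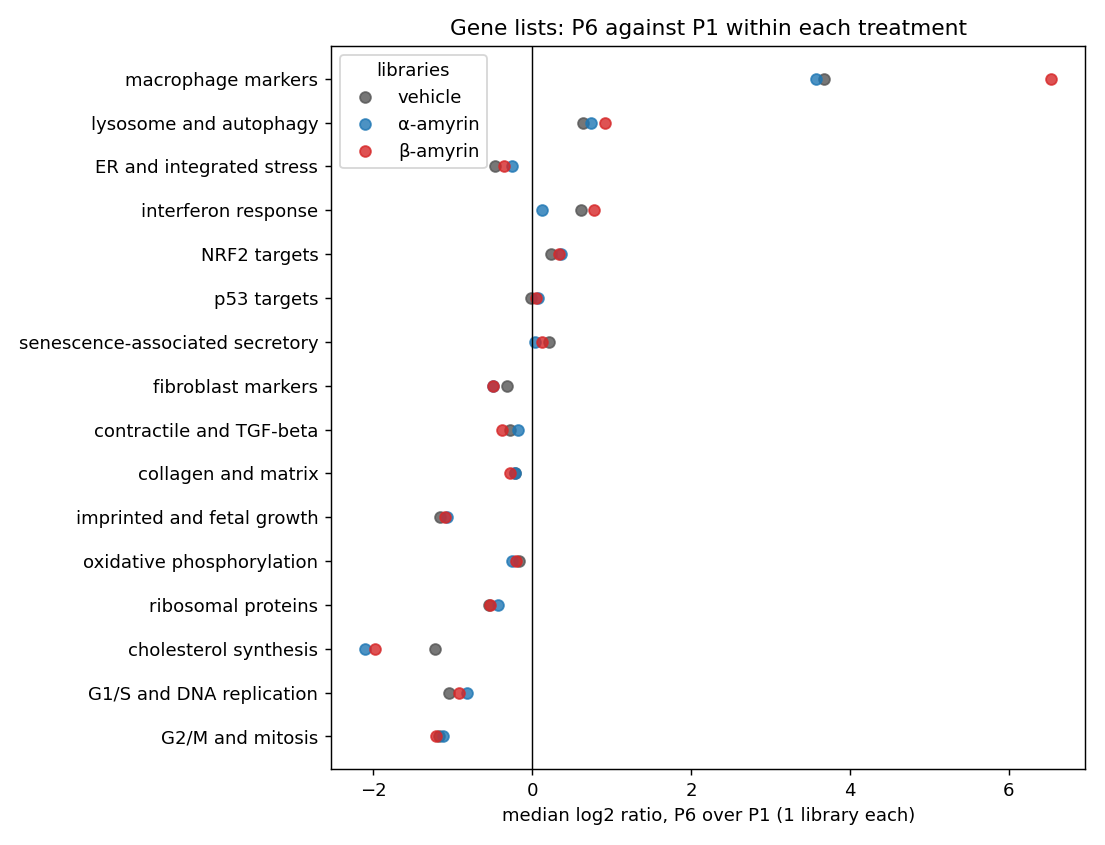
Each point is the median log2 ratio of a gene list in the P6 library over the P1 library of the same treatment, for vehicle (grey), α-amyrin (blue) and β-amyrin (red); there is 1 library per condition and no error bar. The cholesterol synthesis and mitosis lists lay below 0 and the lysosome list above 0 in all 3 treatments, and the macrophage list was highest in the β-amyrin pair.

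Of the remaining lists, 12 of 18 adipocyte differentiation genes rose and 1 fell, among them the lipid droplet gene Plin2, which rose by 1.34. Macrophage markers rose by a median of 4.12 in the same libraries. Over the 12 of these genes with mean CPM at least 5, the P1 α- over β-amyrin ratio was set against the P6 over P1 vehicle ratio. Their Spearman correlation across genes was 0.73. Of the 12, 2 were both at least 2-fold lower in the P1 β- than the P1 α-amyrin library and at CPM at least 5 in either. Without that CPM minimum, 3 of the 18 genes were at least 2-fold lower there and 0 at least 2-fold higher. Of 38 listed histone genes only 7 were measured, and 5 of these rose. The libraries were of poly(A) RNA, so histone transcripts without a poly(A) tail were not assessed. Of 22 ligand and target genes of the WNT, Notch and hedgehog pathways 11 fell and 3 rose, and of 32 immediate early genes 19 fell and 6 rose. The histone median of 0.65 in the vehicle pair and the immediate early median of -0.14 in the α-amyrin pair lay within the range of matched lists. By camera the adjusted p values were 0.00236, 0.0123, 0.015 and 0.0348, and with an estimated correlation the adjusted p values were 0.339, 0.339, 0.339 and 0.536. Not called were the core senescence genes (6 of 22 rose, 13 fell, adjusted p = 0.0678), LXR target and fatty acid synthesis genes, a mixed list (9 of 24 rose, 14 fell, 0.152), heat shock genes (5 of 25 rose, 12 fell, 0.0789), NF-kB targets (13 of 32 rose, 6 fell, 0.129), mitochondrially encoded genes (1 of 12 rose, 1 fell, 0.384), AHR targets (6 of 12 rose, 3 fell, 0.306) and hypoxia and glycolysis genes (9 of 32 rose, 10 fell, 0.813).

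In all, 5095 genes were higher and 4939 lower at P6 by edgeR (adjusted p below 0.05), of which 1684 and 1117 differed at least 2-fold. By size alone, 950 genes were higher and 651 lower in the P6 vehicle library than in the P1 vehicle library. The corresponding counts were 970 and 674 for the α-amyrin pair and 964 and 657 for the β-amyrin pair. With an estimated correlation no list of the 32 was called.

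The second comparison asked what α-amyrin changed against vehicle. By size, 35 genes were higher and 21 lower at P1, and 14 higher and 29 lower at P6. edgeR called 5 genes, 2 higher and 3 lower, each with an adjusted p of 0.0424. The noncoding H19 (ENSMUSG00000000031, mm10 chromosome 7, 142575529 to 142578143) rose by 0.58 ± 0.05, from 5768 to 8508 CPM at P1 and from 617 to 938 CPM at P6. The second gene that rose, the predicted gene Gm27483, named here after its values were seen, lies inside H19 and cannot be counted apart from it without strand. Piezo2, a mechanically gated ion channel, fell by 0.76 ± 0.06, Itga11, a collagen-binding integrin, fell by 0.71 ± 0.06, and the kinesin gene Kif26b fell by 0.76 ± 0.07. By size, the largest increases found at both passages, none of them called, were in Arhgap20, Agtr2, Aqp1, Penk and Dusp27; Agtr2, the type 2 angiotensin receptor, went from 14.7 to 51.0 CPM at P1 and from 13.4 to 24.1 CPM at P6. The largest decreases were in Gjb2, Piezo2, Fndc1, Kif26b and Parm1; Gjb2, a gap junction protein, went from 64.5 to 27.3 CPM at P1 and from 22.3 to 8.28 CPM at P6, a log2 change of -1.33 ± 0.15 that was not called.

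Matrix and contractile genes were lower with α-amyrin. Of 58 collagen and matrix genes 25 were lower and 4 higher when adjusted over the list alone, and none over all genes. The median ratio to vehicle was -0.15 at P1 and -0.15 at P6, below all 10000 matched lists at both passages. Of 36 contractile and TGF-beta-responsive genes 14 were lower and 1 higher over the list alone, and 1, Itga11, was lower over all genes. Among 20 imprinted and fetal growth genes 8 were higher and 2 lower over the list alone; Igf2 had a log2 change of 0.55 ± 0.07 (edgeR adjusted p = 0.074). Mitosis and replication genes had medians of 0.14 and 0.18 in the fit, with no member passing; the replication median was 0.12 at P1 and 0.29 at P6. Of 56 ribosomal protein genes 11 were higher and 1 lower over the list alone (camera adjusted p = 1.79e-13; adjusted p = 0.523 with an estimated correlation). With the preset correlation the camera adjusted p values were 1.97e-11 for matrix, 1.34e-11 for contractile, 0.000263 for imprinted, 2.96e-10 for mitosis and 1.71e-13 for replication genes. With an estimated correlation the adjusted p values were 0.354, 0.523, 0.524, 0.354 and 0.524.

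The other lists called with α-amyrin at the preset correlation were oxidative phosphorylation (median 0.12, camera adjusted p = 1.45e-07), the unfolded protein and integrated stress responses (-0.07, 0.00114), p53 targets (0.04, 0.00717), interferon-stimulated genes (0.14, 0.00802), NRF2 targets (-0.06, 0.016) and cartilage and bone genes (-0.05, 0.0474). With an estimated correlation the adjusted p values were 0.524, 0.791, 0.523, 0.838, 0.523 and 0.586. In the fit 5 of 44 stress response genes were lower over the list alone and none over all genes. In single libraries the medians of 3 of these differed between passages, a difference not tested for α-amyrin alone. The stress response median was -0.24 at P1, with 37 lower and 7 higher and below all matched lists, and 0.03 at P6. The interferon median was 0.39 at P1 and -0.07 at P6, and the cartilage and bone median 0.07 and -0.34. The NRF2 median was -0.10 at P1 and -0.02 at P6, the latter within the range of matched lists.

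None of the 15 genes named in every comparison was called with α-amyrin, with log2 changes from -0.72 for Hmgcs1 to 0.77 for Cxcl1. Cdkn2a had a log2 change of -0.07 (95% interval -0.24 to 0.10) and Cdkn1a by 0.11 (-0.01 to 0.22). Lmnb1 had a change of 0.19 (0.02 to 0.36, edgeR adjusted p = 0.38) and Mki67 by 0.02 (-0.16 to 0.20). The edgeR count of 5 depended on single libraries: it was 332 without the P1 β-amyrin library, 367 without the P6 β-amyrin library, 25 without the P1 vehicle library and 0 without the P1 α-amyrin or the P6 vehicle library. Without the P6 α-amyrin library it was again 5, but none of these were the 5 genes called with all libraries. DESeq2 called 194 genes and limma on log2(FPKM + 1) none, and 1995 genes had an unadjusted p below 0.05 in edgeR.

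The third comparison asked what β-amyrin changed against vehicle. By size, 4 genes were higher and 100 lower at P1, and 27 higher and 77 lower at P6. edgeR called 1 gene, the antisense transcript gene Uchl1os (ENSMUSG00000087601, mm10 chromosome 5, 66626495 to 66676498, minus strand), which is named here after its values were seen because its mean CPM was below 5. Uchl1os had 252 and 147 counts in the P1 and P6 β-amyrin libraries and 4 to 12 counts in the others, and it rose by 4.30 ± 0.26 on the log2 scale (edgeR adjusted p = 0.0165). It overlaps the start of the protein-coding Uchl1, which had 48.8 to 50.7 CPM at P1 and 60.7 to 67.6 CPM at P6. By size, the largest decreases at both passages, none of them called, were in Csf1r, Arrb2, Ucp2, Mt2 and Ctsc; Csf1r went from 51.9 to 9.93 CPM at P1 and from 573 to 240 CPM at P6. The largest increases were in Aqp1, Pin4, Psme2, Adm and Rgs16, at 0.51 to 0.62.

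Macrophage markers were lower with β-amyrin. At P1 all 19 were below vehicle, with a median ratio of -3.25, and at P6 16 of 19 were, with a median of -0.52; both medians lay below all 10000 matched lists. Adjusted over the list alone 4 markers were lower, and over all genes none. With α-amyrin the medians were 0.01 and 0.11. Interferon-stimulated genes also had lower medians with β-amyrin, -0.57 at P1 and -0.23 at P6, with 6 of 53 lower over the list alone. Lysosome genes had medians of -0.22 and 0.06. The camera adjusted p values were 1.8e-13 for macrophage markers, 1.8e-13 for interferon-stimulated genes and 0.000324 for lysosome genes, and with an estimated correlation the adjusted p values were 0.414, 0.464 and 0.519. Of 56 ribosomal protein genes 15 were higher over the list alone (camera adjusted p = 2.73e-21; adjusted p = 0.414 with an estimated correlation).

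Mitosis and replication genes had medians of 0.09 and 0.10 with β-amyrin, with no member passing (camera adjusted p = 0.000222 and 3.57e-06; adjusted p = 0.414 and 0.464 with an estimated correlation). The other lists called at the preset correlation with a positive median were oxidative phosphorylation (0.08, camera adjusted p = 3.76e-10), immediate early genes (0.17, 1.24e-08), p53 targets (0.11, 6.64e-06), imprinted genes (0.13, 0.00226), heat shock genes (0.06, 0.00525) and core senescence genes (0.08, 0.0321). Those with a negative median were mitochondrially encoded genes (-0.16, 0.00132), adipocyte differentiation (-0.10, 0.0121) and matrix genes (-0.04, 0.0172). With an estimated correlation the adjusted p was 0.473 for the core senescence genes and 0.414 for each of the others. In the P6 pair the mitosis (0.06), heat shock (0.07), core senescence (0.05) and adipocyte (-0.09) medians lay within the range of matched lists. So did the mitochondrially encoded median of -0.06 in the P1 pair.

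None of the 15 genes named in every comparison was called with β-amyrin, with log2 changes from -0.82 for Hmgcs1 to 0.44 for Cxcl1. Cdkn2a had a log2 change of -0.06 (95% interval -0.23 to 0.11), Cdkn1a by 0.09 (-0.03 to 0.21), Lmnb1 by 0.16 (-0.02 to 0.33) and Mki67 by -0.15 (-0.33 to 0.03). The edgeR count of 1 was 233 without the P1 β-amyrin library, 317 without the P6 β-amyrin library, 26 without the P1 vehicle library and 0 without the P1 α-amyrin, P6 α-amyrin or P6 vehicle library. DESeq2 called 114 genes, limma on log2(FPKM + 1) called none, RLE size factors gave 3, and 1739 genes had an unadjusted p below 0.05 in edgeR.

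Genes of cholesterol synthesis were lower with both compounds, most of all at P6. The median ratio to vehicle of the 27 genes was -0.15 with α-amyrin and -0.35 with β-amyrin at P1, and -1.17 and -1.15 at P6, where all 27 were below vehicle with each compound. At P6 Hmgcs1 had 221 CPM with vehicle, 91.2 with α-amyrin and 90.8 with β-amyrin. Adjusted over the list alone, 16 genes were lower with α-amyrin and 24 with β-amyrin, and none over all genes. By camera the adjusted p values were 6.21e-16 and 7.26e-22, and with an estimated correlation the adjusted p values were 0.524 and 0.414. Of 24 LXR target and fatty acid synthesis genes, 4 were lower and 2 higher with α-amyrin and 11 lower with β-amyrin over the list alone (camera adjusted p = 2.06e-05 and 8.66e-14; adjusted p = 0.524 and 0.414 with an estimated correlation).

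**Figure D3:**
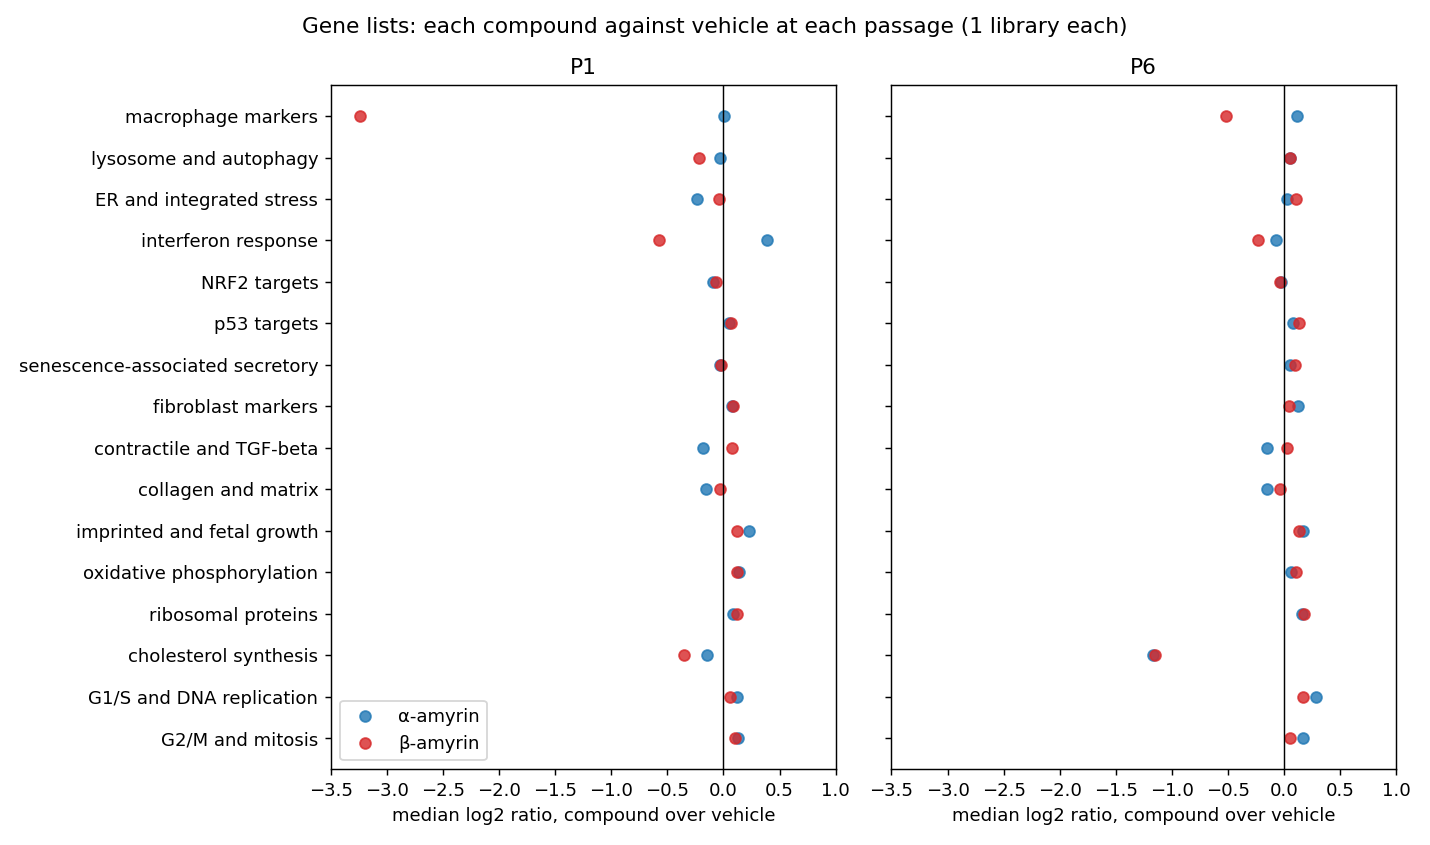
Each point is the median log2 ratio of a gene list in the library of a compound over the vehicle library of the same passage, for α-amyrin (blue) and β-amyrin (red) at P1 (left) and P6 (right); there is 1 library per condition and no error bar. The macrophage list lay at -3.25 with β-amyrin at P1 and the cholesterol synthesis list at -1.17 and -1.15 with the compounds at P6.

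**Figure D4:**
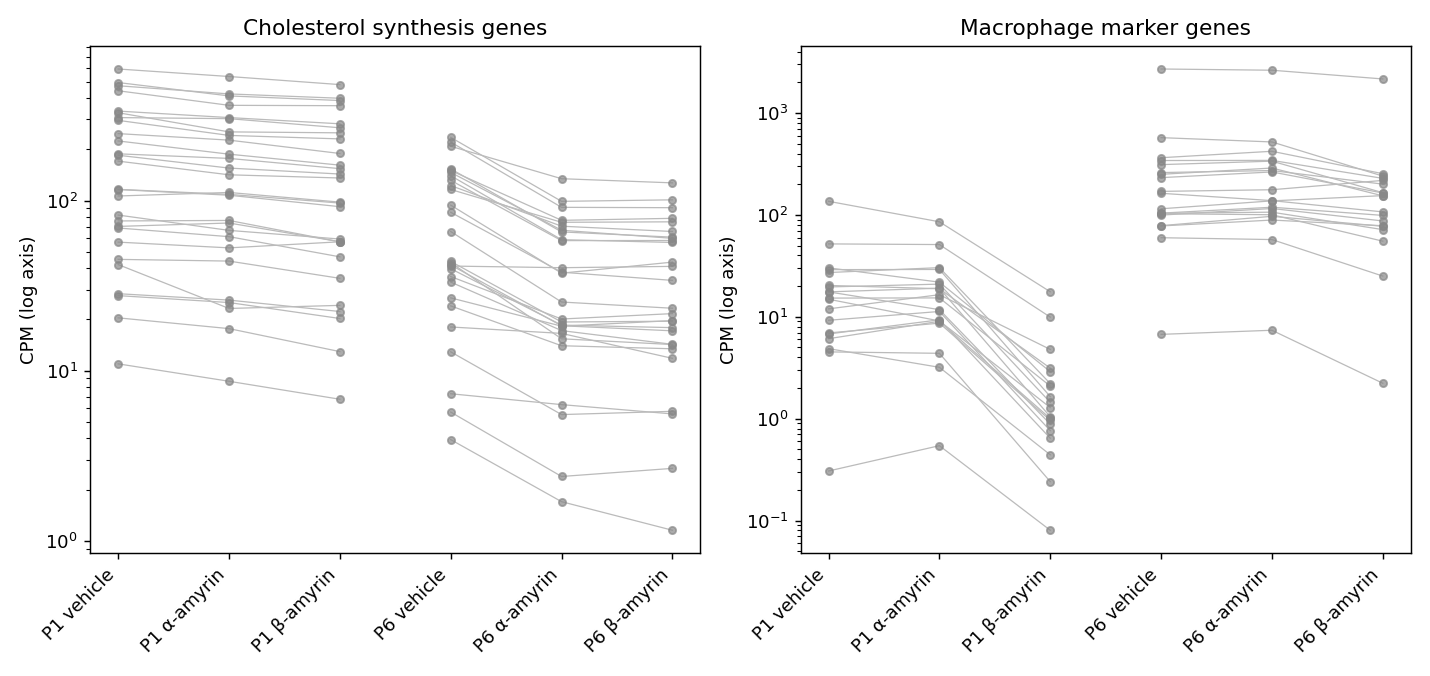
Each point is a gene of the cholesterol synthesis list (left, 27 genes) or the macrophage marker list (right, 19 genes) in 1 library, in CPM on a log axis, with lines joining a gene within a passage. The cholesterol genes were lower at P6 and lower again with each compound there, and the macrophage markers were lowest in the P1 β-amyrin library.

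The fourth comparison set the isomers against each other at the same dose and time. By size, 124 genes were higher and 4 lower with α- than with β-amyrin at P1, and 65 higher and 15 lower at P6. edgeR called 10 genes, 8 higher with α-amyrin and 2 higher with β-amyrin. Lpl, lipoprotein lipase, was higher with α-amyrin by 1.28 ± 0.10 (adjusted p = 0.0202), with 96.2 against 33.6 CPM at P1 and 578 against 274 CPM at P6. Selenop, a secreted selenoprotein, differed by 1.07 ± 0.06 (adjusted p = 0.00588), Ucp2, a mitochondrial carrier, by 0.97 ± 0.08 and the integrin gene Itga6 by 0.76 ± 0.06. The others were Ccdc152, Unc93b1, Cd72 and Dab2, and Ccdc152 overlaps Selenop, so their reads may not be separable. Macrophage markers were also higher with α- than with β-amyrin, with medians of 3.06 at P1 and 0.57 at P6. Whether the 8 genes higher with α-amyrin followed macrophage content was not tested. Rpl7a, a ribosomal protein gene with many copies, differed by -0.81 ± 0.07, and Uchl1os by -5.28 ± 0.30. By size, Slc7a11, Rgs4, Ptgs2 and Cnn1, none of them called, had the largest values in the β-amyrin direction at both passages besides Rpl7a.

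Contractile genes were lower and interferon-stimulated genes higher with α-amyrin than with β-amyrin. Adjusted over the list alone, 22 of 36 contractile genes were lower and 1 higher, 19 of 58 matrix genes were lower and 2 higher, and 19 of 53 interferon-stimulated genes were higher. Over all genes none of these passed. The medians of the difference were -0.21, -0.11 and 0.63. Of 19 macrophage markers 4 were higher over the list alone, with a median of 1.17. In single libraries these medians differed in size between passages, which was not tested. The interferon median was 1.02 at P1, with 53 of 53 genes higher, and 0.20 at P6, with 38 higher and 15 lower. The macrophage median was 3.06 at P1 and 0.57 at P6. The contractile median was -0.24 and -0.17. With the preset correlation the camera adjusted p values were 7.9e-19, 8.67e-08, 1.04e-23 and 3.38e-14, and with an estimated correlation the adjusted p was 0.608 for each. Lists also called were the stress responses (median -0.11, camera adjusted p = 4.92e-09), immediate early (-0.19, 7.83e-05), heat shock (-0.07, 0.00484), adipocyte (0.16, 0.00484) and mitosis genes (0.07, 0.00364), with an adjusted p of 0.608 for each with an estimated correlation. Lysosome (0.08, 7.83e-05), replication (0.08, 0.00143), LXR target and fatty acid synthesis (0.06, 0.00364) and mitochondrially encoded genes (0.07, 0.0398) had adjusted p values of 0.712, 0.727, 0.697 and 0.697 with an estimated correlation. The mitochondrially encoded median was -0.08 at P1, within the range of matched lists, and 0.19 at P6. The lysosome median was 0.16 at P1 and 0.0032 at P6, and the LXR target and fatty acid synthesis median 0.15 and 0.03. Both lay within the range of matched lists at P6. So did the adipocyte median at P6, the mitosis median at P1 and the heat shock median at both passages.

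Between the isomers, the cholesterol synthesis list had a median difference of 0.18 at P1, with 25 of 27 higher with α-amyrin, and 0.05 at P6, with 16 of 27. Hmgcs1 differed by 0.10 (95% interval -0.47 to 0.67), an interval that leaves room for a difference of over 0.5 in the α-amyrin direction. No member of the list passed over all genes or over the list alone, and the list was called with a median difference of 0.12 at the preset correlation only (camera adjusted p = 0.0447; adjusted p = 0.808 with an estimated correlation). Cdkn2a differed by 0.00 (-0.17 to 0.17). The count of 10 was 188 without the P1 β-amyrin library, 439 without the P6 β-amyrin library, 4 without the P1 vehicle library and 0 without the P1 α-amyrin library. DESeq2 called 119 genes and limma on log2(FPKM + 1) none.

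The fifth comparison asked whether the response to amyrin differed between passages, with α- and β-amyrin taken as alike. edgeR called no gene. The smallest adjusted p was 0.467, 451 genes had an unadjusted p below 0.05, DESeq2 called 21 genes and limma on log2(FPKM + 1) none. Without the P1 α-amyrin library edgeR called 16 genes. Each vehicle group had 1 library and was fitted exactly, so the error of this fit came only from α- against β-amyrin within a passage. A P6 vehicle library that stood apart by itself would therefore count as a response. Of the cholesterol synthesis list, 21 of 27 genes responded more negatively at P6 when adjusted over the list alone, with a median difference of -0.88. Hmgcs1 differed by -1.06 ± 0.13 (edgeR adjusted p = 0.467 over all genes). In a list test added after the data were seen, the camera adjusted p was 1.16e-41, and with an estimated correlation the adjusted p was 0.85.

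Compound effects measured with no library in common were correlated across 10669 genes, which are not independent replicates. For the same compound at the 2 passages Pearson's r was 0.34 with α-amyrin (Spearman's rho 0.33) and 0.27 with β-amyrin (0.27). Between different compounds r was 0.21 for α-amyrin at P1 and β-amyrin at P6 (0.23) and 0.16 for β-amyrin at P1 and α-amyrin at P6 (0.18). Pairs that share a vehicle library had r of 0.45 at P1 and 0.63 at P6, against 0.50 and 0.49 in simulations with no compound effect. Their covariances were 0.0165 and 0.0219 against 0.0153 and 0.0155 simulated, and with 1 vehicle library per passage part of the excess at P6 may come from the shared library.

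The last comparison asked whether the compounds moved passage-changed genes at P6. Only genes with CPM at least 5 in every library entered the sets, which leaves out genes near 0 at either passage. The sets are therefore smaller than the 964 higher and 657 lower genes by size in the β-amyrin pair. With α-amyrin, 473 genes at least 2-fold higher at P6 in the β-amyrin libraries had a median ratio to vehicle of 0.07, above all matched lists, and 424 lower genes had a median of 0.01, within the range of matched lists. With β-amyrin, 442 genes higher at P6 in the α-amyrin libraries had a median of -0.05, below all matched lists, and 423 lower genes had a median of 0.02, within the range. All 19 macrophage markers, which were higher at P6, had medians of 0.11 with α-amyrin and -0.52 with β-amyrin at P6. The 19 were taken without that CPM minimum, so these may not be the medians of markers within the sets. For genes at least 4-fold higher at P6 the medians were 0.12 with α-amyrin and -0.32 with β-amyrin. For genes at least 4-fold lower at P6 the medians were -0.31 with α-amyrin and -0.15 with β-amyrin when the genes were chosen in the libraries of the other compound, and 0.03 and 0.10 when they were chosen in the vehicle libraries. Neither choice is neutral: cholesterol synthesis genes had P6 over P1 medians of -2.10 and -1.98 in the α- and β-amyrin pairs, against -1.22 with vehicle, so genes lowered by both compounds can enter the first sets, and the second sets share the P6 vehicle library with the ratio.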

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

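All tests of explanations in this part were chosen after the results were seen. The response to amyrin differed between passages for 7 gene lists in the camera test with the preset correlation, and for none with an estimated correlation (smallest adjusted p = 0.851). The error of that fit held no spread between vehicle libraries. The median log2 difference, P6 against P1, was 0.13 for replication genes, -0.88 for cholesterol synthesis, -0.11 for LXR target and fatty acid synthesis genes, 0.22 for the unfolded protein and integrated stress responses, 0.19 for lysosome genes, -0.029 for nuclear genes of oxidative phosphorylation and 0.55 for macrophage markers. In pairs of single libraries, the stress response list had a median of -0.0434 with β-amyrin at P1 and 0.11 at P6, and the interferon list had 0.39 with α-amyrin at P1 and -0.0675 at P6; these differences between passages were not tested.

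Macrophage markers had a median log2 ratio to vehicle of -3.25 with β-amyrin at P1 and -0.52 at P6. A smaller share of macrophages as the whole cause at P6 would lower macrophage genes alike. Over the 19 markers the SD of the β-amyrin ratio at P6 was 0.53, against 0.14 with α-amyrin. For these markers that argues against a smaller share as the whole cause. A wider set held 58 genes at least 4-fold lower in the P1 β-amyrin than in the P1 α-amyrin library, with CPM at least 5 in either. Their SDs at P6 were 0.75 with β-amyrin and 0.52 with α-amyrin. With CPM at least 5 in the P6 vehicle or β-amyrin library, 57 genes were left, 47 lower and 10 higher with β-amyrin. The SDs were then 0.39 and 0.17. Over 124 genes at least 2-fold lower they were 0.65 and 0.46. The wider sets therefore decide nothing, because their values depend on the CPM minimum. Cultures that differed in macrophages by chance cannot be told apart from an effect of β-amyrin at P1, because the value of -3.25 comes from 1 library. An effect of β-amyrin on macrophages may also account for it, as an untested hypothesis.

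Cholesterol synthesis genes were lower with both compounds at P6. A smaller share of macrophages is argued against by the macrophage median of 0.11 with α-amyrin, where the cholesterol median was -1.17, against -1.15 with β-amyrin. The lower depth of the P6 α-amyrin library, as a cause common to both compounds, is argued against by the median of -1.15 with β-amyrin. That library had 25440191 counts. With the P6 vehicle library thinned to the α-amyrin depth, the α-amyrin median was -1.12. Thinning followed by scaling was bound to move this median little, so it decides nothing further. A P6 vehicle library that stood apart by itself cannot be told apart from a compound effect: it is the denominator of both ratios, and the median with β-amyrin against the other vehicle library, at P1, was -0.35. A response of sterol-regulated genes to the triterpenes that is larger at P6 may be involved, as a hypothesis.

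Lysosome genes were higher at P6, as were macrophage markers. Across members, the Spearman correlation of the P1 ratio of α- over β-amyrin, which differ in macrophage markers, with the P6 over P1 vehicle ratio was 0.46. The median P1 difference was 0.16, above the 0.0701 that macrophage RNA alone would need, while the 9 members at or below 0 in that P1 ratio still had a median of 0.53 at P6 over P1. More macrophage RNA cannot be told apart from a change within fibroblasts: these values point both ways, and only 4 of the 57 members need a P1 difference of over 2 times the SD of 0.159 of single unlinked genes. The passage that the design names may raise lysosome genes in fibroblasts, which was not tested.

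For the passage counts of 5095 higher and 4939 lower genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest of the other splits was 0. With 10 splits the share cannot fall below 0.05. Each of the other splits mixed P1 and P6 libraries, so the difference between passages entered its error. Their 0 calls would follow from any large difference between P1 and P6, whatever its cause.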

How the results depend on the processing

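Leaving out genes at least 2-fold lower in the P1 β-amyrin than in the P1 α-amyrin library and the list tests of the passage-by-amyrin term were chosen after seeing the data; the other alternatives were planned. The counts of genes higher and lower at P6 stayed within 1.5 times of 5095 and 4939 under every alternative run, at 3738 to 5238 and 4115 to 5217. The cause was not tested for the shifts below unless a value is given.

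The α-amyrin count of 5 became 464 without a low-count filter, 194 with DESeq2, 0 with limma on log2(FPKM + 1), 0 on log2(FPKM + 0.1) and 0 with both compounds as 1 amyrin group, and ranged from 0 to 367 when 1 library was left out. The β-amyrin count of 1 became 3 with RLE size factors, 404 without a filter, 114 with DESeq2, 0 on both FPKM scales and 0 with 1 amyrin group, and ranged from 0 to 317. The count of 10 between the isomers became 484 without a filter, 119 with DESeq2, 0 on both FPKM scales and 5 without the genes lower in P1 β-amyrin, which by construction takes away calls in that direction, and ranged from 0 to 439. The passage-by-amyrin count of 0 in edgeR, with 451 genes at an unadjusted p below 0.05, became 159 without a filter and 21 with DESeq2, was 0 with limma on both FPKM scales, and ranged from 0 to 16; leaving out a vehicle library left no passage-by-amyrin term to estimate. The prior degrees of freedom of the edgeR fit of treatment and passage rose from 4.83 to 29 without the filter, 12.5 without the P1 β-amyrin library and 13.3 without the P6 β-amyrin library, the settings with the largest counts.

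Counts by size between single libraries moved with the minimum. The reported counts were 1601, 1644 and 1621 for P6 over P1 with vehicle, α-amyrin and β-amyrin, 56 and 104 for the compounds over vehicle at P1, 43 and 104 at P6, and 128 and 80 between isomers. With CPM at least 1 they were 2546, 2611 and 2620 for P6 over P1 with vehicle, α-amyrin and β-amyrin, 192 and 356 for α- and β-amyrin over vehicle at P1, 225 and 282 at P6, and 393 and 217 for α- over β-amyrin at P1 and P6; more genes enter under that minimum. With log2(FPKM + 1) the 6 compound counts were 123 and 217 at P1, 170 and 190 at P6, and 199 and 186 between isomers. With CPM at least 1 the correlations were 0.26 and 0.22 for α- and β-amyrin across passages, 0.16 and 0.0885 across compounds, and 0.41 and 0.59 for pairs sharing vehicle at P1 and P6. Without the genes lower in P1 β-amyrin, that of β-amyrin at P1 with α-amyrin at P6 was 0.18 and that of α- with β-amyrin at P1 was 0.50; the set was defined from the same ratios, so this says nothing of macrophages.

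For passage-changed genes, the α-amyrin median of lower genes reversed to -0.31 at 4-fold and that with β-amyrin to -0.15. With passage change from the vehicle libraries, which share a library by construction, the medians were 0.027 for higher and 0.0888 for lower genes with α-amyrin and 0.092 for lower genes with β-amyrin. At 4-fold the vehicle-derived medians of lower genes were 0.033 with α-amyrin, within the range of matched lists, and 0.0957 with β-amyrin, so the reversal was found only with sets chosen in the libraries of the other compound. mt-Nd6 reversed between P6 and P1 from 0.32 to -0.16 with log2(FPKM + 1) and to -0.16 with log2(FPKM + 0.1). Of 160 list tests, 32 lists in 5 comparisons, 74 were called at the preset correlation. All 160 outcomes were unchanged with RLE size factors. All 74 calls were lost with an estimated correlation (smallest adjusted p = 0.295), and the other 86 stayed uncalled. That test rests on 2 residual degrees of freedom, so the loss does not show that correlation between genes accounts for the calls. For mitosis genes at P6 the estimated correlation was 0.0096, below the preset 0.01, yet the unadjusted camera p went from 1.31e-24 to 0.00922. P6 was compared with P1 within treatment; without the treatment term 4868 genes were higher and 4711 lower. Whether depth or the number of libraries limited the counts was not tested.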

Other observations

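The genes in this part were chosen after their values were seen, and each value is from 1 library with no test of the difference within a passage. Among genes that macrophages and other phagocytes express, several were highest in the P6 β-amyrin library, where most macrophage markers were below vehicle. Gpnmb, a membrane glycoprotein, had 180, 218 and 665 CPM in the P6 vehicle, α-amyrin and β-amyrin libraries, and Lgals3, a galectin, had 187, 207 and 414 CPM. Mmp12, a macrophage elastase, had 9.86, 16.3 and 77.3 CPM, Fabp5, a fatty acid-binding protein, had 32.3, 25 and 78.1 CPM, and Atp6v0d2, a proton pump subunit, had 3.85, 5.52 and 17.0 CPM. At P1 Gpnmb had 73.1, 120 and 62.1 CPM.

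Trib3, Chac1 and Atf3, targets of the integrated stress response, were above vehicle with both compounds at P6. The fixed list of 44 genes that covers this response and the unfolded protein response had a median of -0.24 with α-amyrin at P1, with 37 lower and 7 higher, of 0.03 with α-amyrin at P6, within the range of matched lists, with 26 higher and 17 lower, and of 0.11 with β-amyrin, with 34 higher and 10 lower. Trib3 had 4.44 CPM with vehicle, 12.6 with α-amyrin and 15.4 with β-amyrin at P6, and 45.5, 29.5 and 36.8 CPM at P1. Chac1 had 6.77, 11.8 and 13.1 CPM at P6 and 29.2, 20.6 and 25.3 CPM at P1, and Atf3 had 11.1, 21.8 and 26.7 CPM at P6. The interferon-induced Ifit1 had 4.87, 12.1 and 3.58 CPM at P1 and Ifit3 had 2.61, 7.82 and 1.73 CPM.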
